A study of Mus musculus with 3 samples.

How the data were processed

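Live CD45+ cells were sorted from liver tumours of MYC-ON mice and made into 10x 3' v3 libraries, 1 each for control, DU101 and DU102. The matrices deposited by the authors hold raw counts of UMIs for 32285 features, made with Cell Ranger 6.0.0 per the file headers, while the submitters' notes name Cell Ranger 2.1.1 and mm10. The annotation release is not given in the sources used here. The barcodes had already been limited to called cells, since the lowest total was 500 UMIs in every library. A table of log2 fold changes by numbered cluster, deposited by the authors for each library, lists selected genes, assigns no barcode to a cluster and was not used.

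Cells were kept with at least 200 genes and at most 10% mitochondrial UMIs. More than 10% mitochondrial UMIs were found in 17.4, 9.09 and 14.0% of barcodes in control, DU101 and DU102. Doublets were called per library, among cells with at least 200 genes and at most 20% mitochondrial UMIs, with Scrublet in scanpy 1.11.5, at a rate of 0.008 per 1000 barcodes, and removed. They made up 2.53, 3.14 and 2.06% of the cells they were called among, and 265, 458 and 249 of them were within the limit of 10%. The remaining 35414 cells were scaled to 10000 UMIs, log-transformed and clustered jointly, without integration, on 2000 variable genes, 30 principal components and 15 neighbours, by Leiden at resolution 1.0. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes were kept out of the variable genes, a step added to the plan afterwards. Clusters took the name of the best-scoring of 23 marker sets, or no name. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.

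Class shares are percent of cells with exact Clopper-Pearson 95% intervals. For gene expression, UMIs were summed by library and class and given as CPM, which are counts scaled to the same total in every class and library, with the exact interval of the ratio of a pair of Poisson counts, in the 10 classes with at least 200 cells in every library. A gene counted as higher or lower by size at 1.5-fold or more with the interval on that side of 1, which is not a test. A ratio against 0 counts was taken against a floor of 3 counts. For 26 gene lists, the median log2 ratio of the members with at least 30 UMIs over both libraries was placed among 10000 random lists matched on expression, where at least 5 members were measured. With 1 library per group, no test between groups was made.

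Genes were named by rule: in each class, the 2 genes highest and the 2 lowest in each treated library over control, ranked by the end of the interval nearest to 1. They needed at least 30 UMIs and 50 CPM in the higher library and at least 0.25 of the gene's highest class CPM there. Mitochondrial, ribosomal, haemoglobin and receptor segment genes, numbered gene models, hepatocyte genes and the sex-linked list were left out. For lists, the members with the largest log2 ratios were named. Cd274, Ptprc and Myc were fixed for every class. The comparisons, filters, marker sets, gene lists, naming rules and a first set of alternatives were chosen before the data were examined. The score that assigns markers to clusters was set, and revised for other clusterings, after they were seen. The plan was to print every list beyond the percentiles, but about 50% passed. A narrower choice was therefore made with the values in view: lists beyond the percentiles on one side in at least 5 classes, and per class the list furthest from the median of all genes. The lists of hepatocyte, erythroid and sex-linked RNA served as checks and were left out of that ranking, as were granule genes outside neutrophil-like cells, a choice also made with the values in view.

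The calls were tested on simulated data drawn from the rates of control T-like cells at the depth of DU101. The real data had already been analysed when this test was written. Of 100 genes set to 2-fold, 99.0% were called in the right direction, and of 100 set to 4-fold, 100.0%. Of 11119 unchanged genes, 1.03% were called by size, and 95.9% of intervals held a ratio of 1. Apart from the changed genes, both libraries were drawn as Poisson counts from the same rates, as the intervals assume. These values therefore check the calculation under counting error only. The draws hold no difference between animals, in cell make-up or in carried-over RNA, so the values are no error rate for the real calls. Of unchanged lists of 14 genes, 6.5% lay at or beyond the 2.5th or 97.5th percentile, where such limits allow 5%. Too few lists were drawn to tell these values apart, and each was placed among fewer random lists than the real ones.

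Sex was read from Xist and from Ddx3y, Eif2s3y, Kdm5d and Uty. In each cluster, the male part of control was estimated as its cells multiplied by the ratio of Y-linked CPM in control over the treated libraries together, capped at all cells, which takes the treated animals as male. T-like cells were also thinned to 1000 and to 500 UMIs per cell for the shares of cells with a marker UMI, leaving out shallower cells (22, 99 and 58 at 1000). Alternatives fixed beforehand were at least 500 genes, at most 5% or 20% mitochondrial UMIs, doublets kept, resolution 0.5 or 2.0, each library clustered on its own, edgeR TMM factors, every cell weighted alike, totals without carried-over and housekeeping RNA, a minimum of 100 or 10 UMIs, and a size rule of 2-fold. Alternatives added after the data were seen were the 2 largest clusters, each alone, of neutrophil-like (15 and 17), T-like (4 and 6), NK-like (7 and 20) and hepatocyte or tumour-like cells (25 and 29), control cells with Y-linked UMIs and no Xist, the estimated male part of control, and shares without low-UMI hepatocyte or tumour-like and unnamed clusters.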

Results

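Single-cell RNA was counted in 3 libraries of live CD45+ cells, sorted by flow cytometry from liver tumours of C57BL6 MYC-ON mice at 18 weeks of age. Each of the 3 groups (control, DU101 and DU102) has 1 library. CD45, encoded by Ptprc, is carried by white blood cells. What DU101 and DU102 are, their dose and duration, and the number and sex of the animals in each library are not given in the sources used here. The control library is labelled CONTROL while its data carry the name DMSO, and what the control animals were given is not stated. The barcodes numbered 12639 in control, 15686 in DU101 and 13650 in DU102. Total counts of RNA molecules (UMIs) were 91013198 in control, 106604935 in DU101 and 96817875 in DU102, with a median of 5148, 4499.5 and 4388.5 UMIs per barcode in the same order. After filtering, 10154 control, 13799 DU101 and 11461 DU102 cells remained, with medians of 6336, 4832 and 5091 UMIs. With 1 library per group, no difference between groups has a replicate check. Values in brackets are 95% intervals, exact binomial (Clopper-Pearson) for shares and exact Poisson for ratios of counts, and they cover counting error only.

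The libraries differed in sex-linked RNA. Xist, a non-coding RNA made from the inactive X chromosome of female cells, was seen in 56.0% of control cells, 0.138% of DU101 cells and 0.0698% of DU102 cells. RNA of Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) was seen in 21%, 46.8% and 52.5%. Among control cells, 5390 held Xist alone, 1834 held Y-linked RNA alone and 299 held both, so the control library mixed cells of animals of both sexes while the treated libraries were almost free of Xist. The Y-linked signal put an estimated 40.0% of control cells in male animals, and this part differed by class. It was 100% of neutrophil precursor-like cells and 67.0% of neutrophil-like cells, against 29.9% of T-like, 25.8% of NK-like and 14.2% of plasmacytoid dendritic cell (pDC)-like cells. Sex therefore goes with treatment in every comparison against control. The share estimated for the male part of control is given with the class shares, as a point estimate without its own counting error. Tsix, which lies antisense to Xist, was among the genes furthest below control in 7 of the 10 classes examined in both treated libraries, and its reads cannot be separated from this difference in sex.

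The cells formed 31 clusters, of which 27 took names from marker genes fixed in advance. The names were rebuilt from markers here and are given as likenesses. They made 19 classes, and 4 clusters stayed unnamed, with 4.87% of control, 2.80% of DU101 and 4.17% of DU102 cells. The largest classes in control were T-like cells (16.3%), NK-like cells (13.9%), neutrophil-like cells (12.3%) and monocyte-like cells (11.8%). Hepatocyte or tumour-like, endothelial-like and stellate or fibroblast-like cells do not carry CD45, and red cells were lysed before the sort, so the sort and lysis can set the shares of these classes and of erythroid-like cells. The 10 classes with at least 200 cells in each library were used for gene expression.

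**Figure D1:**
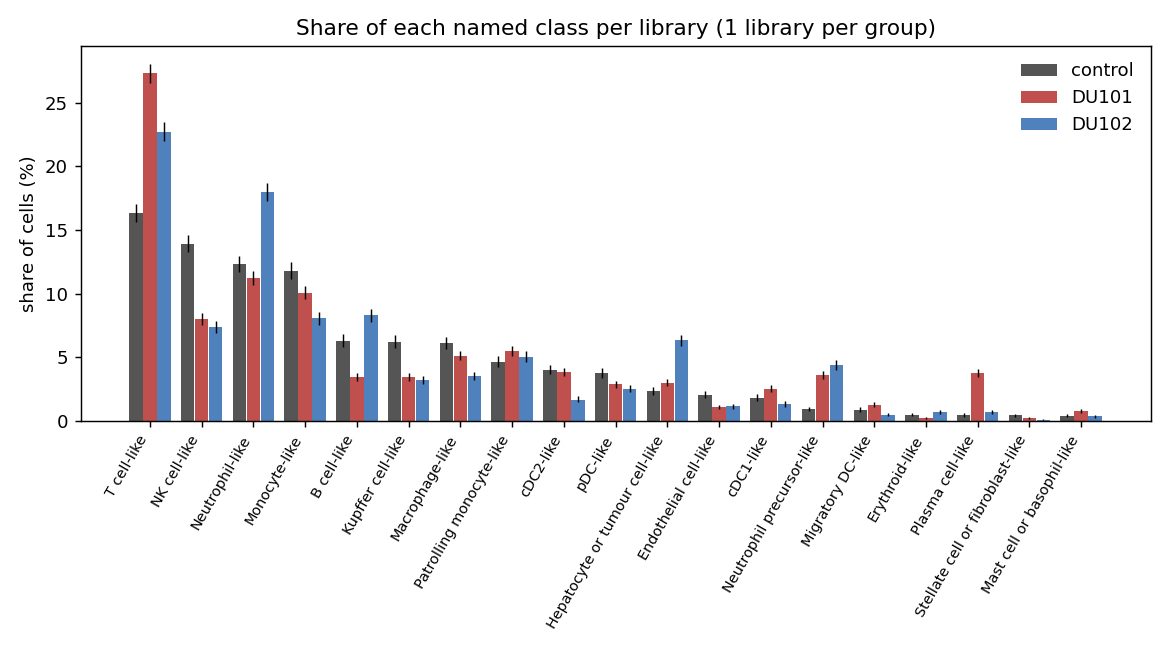
Share of cells in each named class (percent of cells, vertical axis) in the control, DU101 and DU102 libraries, with 95% Clopper-Pearson intervals as error bars. T-like cells made up 16.3%, 27.3% and 22.7%, and NK-like cells 13.9%, 7.97% and 7.38%.

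DU101 against control asks how the tumour immune cells of treated animals differ from those of control animals. T-like cells were 1.67 (1.58 to 1.78) times as frequent in DU101, and NK-like cells 0.572 (0.528 to 0.619) times. Plasma-like cells, which secrete antibody, were 8.47 (6.24 to 11.8) times as frequent, and neutrophil precursor-like cells 3.90 (3.12 to 4.92) times. Genes induced by type I interferon were higher in DU101 in all 10 classes, as with Rsad2, an antiviral gene, at 185 against 41.3 CPM, 4.48-fold higher (3.40 to 5.95) in Kupffer-like cells, the resident macrophages of liver. CPM are UMIs of the gene scaled to the same class total in every library.

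T-like cells made up 27.3% (26.6 to 28.1) of DU101 and 16.3% (15.6 to 17) of control cells, with 12.2% estimated for the male part of control. NK-like cells were 7.97% (7.52 to 8.44) against 13.9% (13.3 to 14.6), and their male control estimate of 8.99% left a smaller gap. Plasma-like cells were 3.75% against 0.443%, with 1.11% in male control. B-like cells were lower, at 3.44% against 6.30% with a ratio of 0.546 (0.484 to 0.616) and a male control estimate of 7.84%. Neutrophil precursor-like cells were 3.57% against 0.916% (male control 2.29%). Neutrophil-like cells differed little, at 11.2% against 12.3%, but their male control estimate was 20.7%. Their clusters differed in make-up: cluster 15 held 10.6% of control and 4.28% of DU101 cells, and cluster 17 held 1.73% and 6.93%. Kupffer-like cells were 0.555 times the control share (3.46% against 6.22%; male control 7.43%). Monocyte-like cells were 0.853 (0.789 to 0.922) times, patrolling monocyte-like cells 1.18 (1.05 to 1.32) times and macrophage-like cells 0.842 (0.755 to 0.939) times the control share. Male control estimates were 12.1%, 3.14% and 6.64%, against 10.1%, 5.49% and 5.12% in DU101. When each library was clustered on its own these 3 classes went the other way, with log2 ratios of 0.13, -1.22 and 0.44.

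Among dendritic cells, cDC1-like cells were 1.39 (1.16 to 1.67) times, cDC2-like cells 0.95 (0.834 to 1.08) times and migratory dendritic cell-like cells 1.46 (1.13 to 1.91) times the control share. The male control estimates were 1.26%, 1.48% and 0.168%, against 2.54%, 3.82% and 1.27% in DU101. pDC-like cells, of the kind that makes interferon, were 0.765 (0.663 to 0.883) times the control share, but higher than the male control estimate (2.86% against 1.33%). At up to 5% mitochondrial UMIs their log2 ratio to control was 0.11. Mast cell or basophil-like cells were 2.06 (1.41 to 3.05) times the control share (0.790%, male control 0.623%). Among classes that the CD45 sort or red-cell lysis can set, the ratios to control were 1.28 (1.09 to 1.51) for hepatocyte or tumour-like, 0.528 (0.425 to 0.654) for endothelial-like, 0.548 (0.335 to 0.886) for stellate or fibroblast-like and 0.427 (0.26 to 0.688) for erythroid-like cells. Against the male part of control, the log2 ratios of endothelial-like and stellate or fibroblast-like cells were 1.01 and 0.41, the other way. Their male control estimates were 0.539% and 0.174%, beside 1.83% for hepatocyte or tumour-like and 0.832% for erythroid-like cells. The stellate or fibroblast-like estimate rests on a Y-linked ratio of 0.164 (0.0828 to 0.302), an interval too wide to show a turn. For erythroid-like cells the direction also turned at clustering resolution 0.5 (0.49).

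Of 233 scored pairs of gene list and class, 112 had a median log2 ratio at or beyond the lower or upper percentile limit of 10000 random lists matched on expression, 86 higher and 26 lower. That percentile is a description of these libraries. The 86 include 7 for the sex-linked list and 9 for granule genes, and the 26 include 2 for hepatocyte RNA. Values given for members of a list are log2 ratios. Where a list is called the furthest ranked in a class, its median lay furthest from the median of all genes among lists beyond the limits, leaving out hepatocyte, erythroid and sex-linked RNA and, outside neutrophil-like cells, granule genes. The type I interferon list was the one beyond the limits in the most classes, 10 of 10. Its median log2 ratio was 0.84 in Kupffer-like, 0.78 in T-like, 0.73 in NK-like, 0.71 in hepatocyte or tumour-like, 0.63 in patrolling monocyte-like, 0.61 in pDC-like, 0.59 in monocyte-like, 0.56 in neutrophil-like, 0.53 in macrophage-like and 0.53 in B-like cells. In monocyte-like cells the median was -0.16 when each library was clustered on its own. Against control cells with Y-linked RNA and no Xist it was 1.13 in T-like, 1.16 in NK-like and 1.04 in B-like cells, further from 0. In T-like cells it was 0.55 and 0.71 in clusters 4 and 6 alone. T-like cluster 5, with Ifit1, Iigp1 and Ifit3 among its top genes, held 0.364% of control, 0.899% of DU101 and 0.297% of DU102 cells. In neutrophil-like cells the list median was 1.32 in cluster 15, which holds most of those in control, and 1.16 in cluster 17, which holds most of those in DU101. The call held under every alternative in 8 of these 10 classes.

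**Figure D2:**
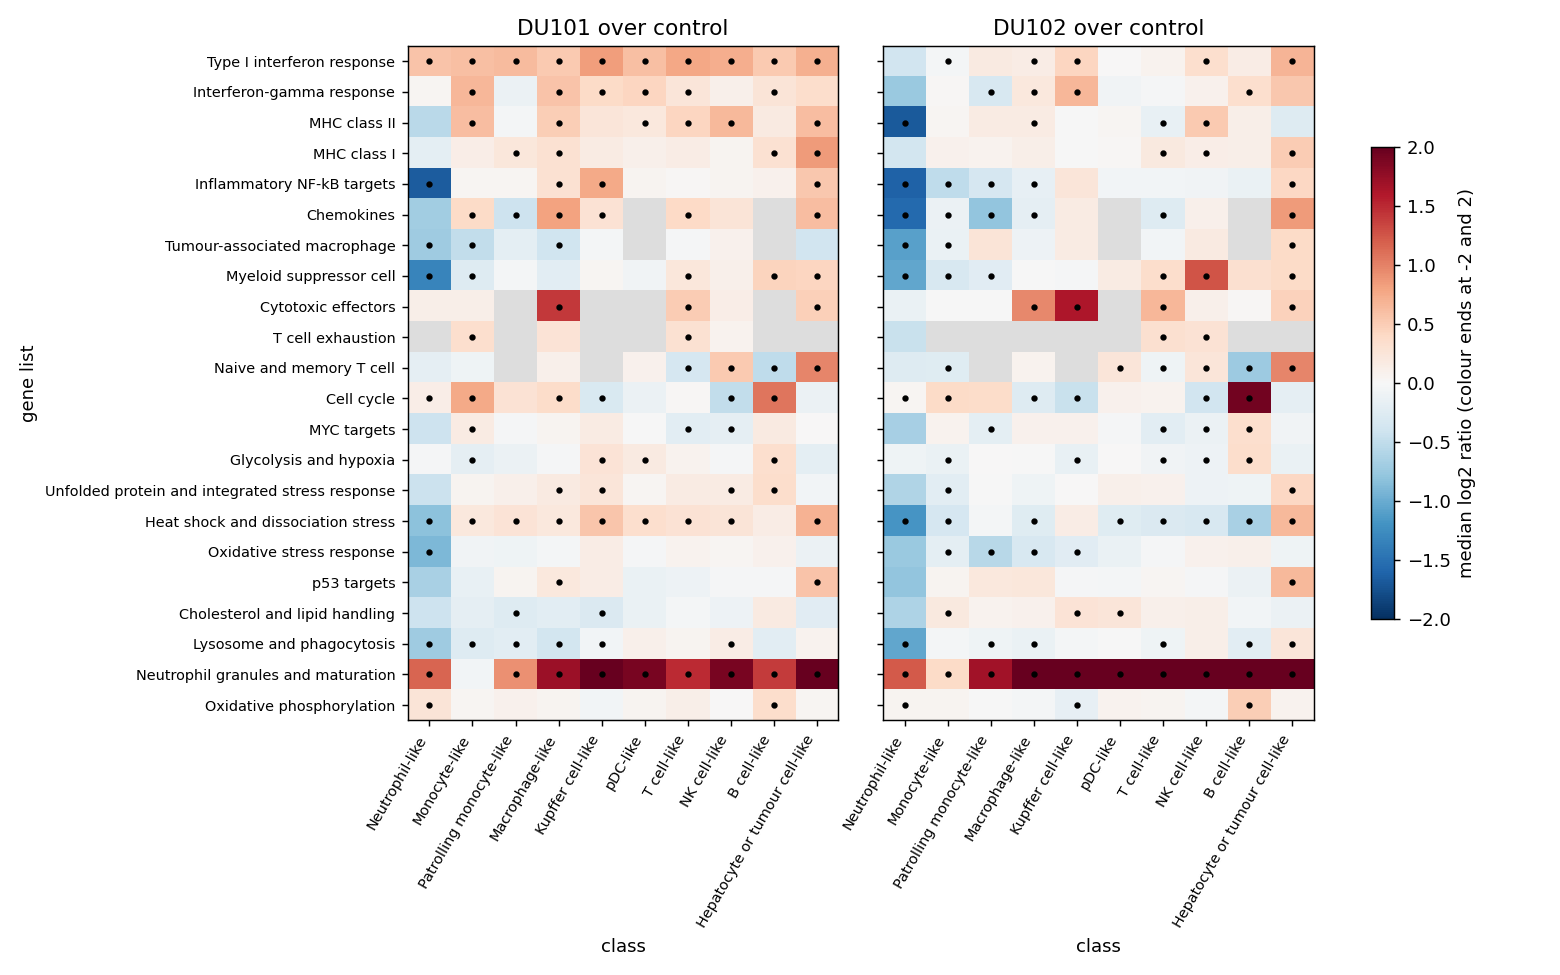
Median log2 ratio of each gene list (vertical axis) in each class (horizontal axis) for DU101 over control and DU102 over control, on a colour scale that ends at -2 and 2. Grey marks lists that were not scored and dots mark medians at or beyond the lower or upper percentile limit of random lists, and the type I interferon line is dotted in 10 of 10 classes for DU101.

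In T-like cells the interferon genes furthest apart were Ifi44, with a log2 ratio of 1.04 (0.36 to 1.78), and Ifit3, with 0.98 (0.81 to 1.16). Ifi27l2a, another interferon-induced gene, was at 2029 against 1072 CPM, 1.89-fold higher (1.85 to 1.93). Trim12a, of a family of near-copy genes whose reads are hard to assign, was at 91.3 against 41.4 CPM, 2.21-fold higher (1.98 to 2.46). In NK-like cells Ifi27l2a had a log2 ratio of 1.39 (1.31 to 1.47). Ccl1, a chemokine, was 88.8 against 31.6 CPM, 2.81-fold higher (2.51 to 3.14), with a log2 ratio of 0.40 when cells were weighted alike and 1.49 and -0.87 in clusters 7 and 20, the larger and the smaller of the 2 NK-like clusters. Klra8 (Ly49H, a receptor on NK cells from a multigene family, so uncertain) was 251 against 95.4 CPM, 2.63-fold higher (2.46 to 2.81). In B-like cells Scimp, an adaptor protein of antigen-presenting cells, was 102 against 28.2 CPM, 3.62-fold higher (2.71 to 4.87), and Crip1 was 1911 against 672 CPM, 2.84-fold higher (2.68 to 3.02). The cell cycle list was the furthest ranked in B-like cells, at 1.07 (granule genes 1.39), with Mki67, a mark of dividing cells, at 2.19 (1.56 to 2.85) and Mcm5 the other way at -0.77 (-1.63 to 0.028). That list was beyond the upper limit in 4 of 10 classes and beyond the lower limit in 2, Kupffer-like and NK-like cells. Its median was -0.42 and 0.088 in NK-like clusters 7 and 20 alone. Lars2, a mitochondrial leucyl-tRNA synthetase, was 3.52-fold lower (3.44 to 3.60) in T-like, 3.13-fold lower (3.03 to 3.23) in NK-like and 3.58-fold lower (3.36 to 3.82) in B-like cells. Gm42418, a gene model that overlaps ribosomal RNA, had log2 ratios of -1.77, -1.67 and -1.74 in the same classes, and both genes were lower than control in all 10 classes of DU101 and of DU102.

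In Kupffer-like cells Isg15, an interferon-induced ubiquitin-like protein, was at 278 against 85.3 CPM, 3.25-fold higher (2.66 to 3.99). Cxcl10, a chemokine that draws T cells, had a log2 ratio of 2.59 (2.02 to 3.20), while Lars2 was 2.22-fold lower (2.09 to 2.36) (Gm42418 log2 ratio -1.37) and Ccr3, a chemokine receptor, 2.20-fold lower (1.61 to 3.06). In macrophage-like cells Ccl8, a chemokine for monocytes, was at 218 against 35.7 CPM, 6.12-fold higher (5.23 to 7.19). Serpina3g, from a multigene family and so uncertain, was 3.51-fold higher (2.71 to 4.58), and Emp1 3.04-fold lower (2.42 to 3.86). The cytotoxic list was the furthest ranked in macrophage-like cells (1.41, beside 1.71 for granule genes, but 0.81 when cells needed at least 500 genes, 0.67 at up to 20% mitochondrial UMIs and 0.61 at resolution 0.5), with Ifng at 3.08 (1.72 to 4.79), a gene of T and NK cells. In monocyte-like cells Hebp1, a heme-binding protein (ENSMUSG00000042770), was at 11.9 against 104 CPM, 8.72-fold lower (7.09 to 10.8), and in patrolling monocyte-like cells at 10.7 against 105 CPM, 9.86-fold lower (6.71 to 15). Cxcl9 and Ifit2, higher by 2.84-fold and 2.66-fold in monocyte-like cells, were lower when each library was clustered on its own (log2 ratios -2.65 and -1.25). Cxcl9 was also lower at up to 20% and 5% mitochondrial UMIs and with doublets kept (-0.78, -0.085 and -0.75). The cell cycle list was the furthest ranked in monocyte-like cells, at 0.76 (sex-linked list 1.00, granule genes -0.053), with Top2a at 1.25 (0.81 to 1.71), and the list median was 0.057 against control cells with Y-linked RNA and no Xist. In patrolling monocyte-like cells Rsad2 was 2.77-fold higher (2.08 to 3.75), with a log2 ratio of 0.66 under separate clustering, and Hes1, a target of Notch signalling, 2.03-fold higher (1.90 to 2.17). In pDC-like cells Fam43a (ENSMUSG00000046546) was at 101 against 3.56 CPM, 28.3-fold higher (15.6 to 57.5). Ccnd1, cyclin D1, was 2.32-fold higher (2.15 to 2.51), and the adhesion gene Cadm1 4.85-fold lower (3.72 to 6.42).

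Lists tied to interferon-gamma and antigen display were higher in several classes. The interferon-gamma list was higher in 6 of 10 classes, with Iigp1, an interferon-induced GTPase, at a log2 ratio of 1.61 (1.21 to 2.03) in macrophage-like cells. In monocyte-like cells its median of 0.66 became -0.48 when each library was clustered on its own and -0.11 at up to 20% mitochondrial UMIs, and the call held under every alternative in 2 of these 6 classes. MHC class II genes, which present antigen to CD4 T cells, were higher in 6 of 10 classes, with H2-Eb1 at 1.61 (1.41 to 1.81) in NK-like and 1.17 (1.13 to 1.20) in macrophage-like cells. Whether the class II RNA of NK-like cells was made there or carried over from other classes was not tested. In monocyte-like cells the class II median was 0.61, but -0.43 with doublets kept. In hepatocyte or tumour-like cells it was 0.62, but -0.22 at up to 5% mitochondrial UMIs and -0.024 when each library was clustered on its own, and the call held under every alternative in 2 of these 6 classes. Chemokines were higher in 5 of 8 classes, with a call that held under every alternative in 0 of these 5, and beyond the lower limit in patrolling monocyte-like cells (-0.42). In monocyte-like cells the median of 0.38 turned in 5 alternatives, and in hepatocyte or tumour-like cells that of 0.62 turned at up to 5% mitochondrial UMIs (-0.30) and with cells weighted alike (-0.58). Genes of heat shock and tissue dissociation were higher in 8 of 10 classes, among them Atf3 at 1.06 (0.88 to 1.23) in NK-like cells. The call held under every alternative in 4 of these 8 classes, and the monocyte-like median of 0.21 was -0.065 at up to 20% mitochondrial UMIs and -0.068 at resolution 2.0. Neutrophil-like cells lay beyond the lower limit (-0.82, with -0.12 and -0.13 in clusters 15 and 17 alone). Lysosome genes were lower in 5 of 10 classes, with the scavenger receptor Cd36 at -0.97 (-1.23 to -0.71) in macrophage-like cells, and beyond the upper limit in NK-like cells (0.15). The call held under every alternative in 3 of these 5 classes, and the neutrophil-like median of -0.71 was 0.086 in cluster 15 and -0.0044 in cluster 17 alone.

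In neutrophil-like cells the median of all genes lay at -0.21, so values there are read against it. Gstp3, a glutathione S-transferase with close relatives and so uncertain, was at 103 against 10.5 CPM, 9.83-fold higher (7.36 to 13.4). Ltf, lactoferrin of the secondary granules, was at 7547 against 2047 CPM, 3.69-fold higher (3.61 to 3.77), though its log2 ratio was 0.64 in cluster 17 alone. Stfa1, one of a set of near-copy stefin protease inhibitors, was at 146 against 1482 CPM, 10.1-fold lower (9.47 to 10.8), with a log2 ratio of -2.36 in cluster 15 alone, and Pik3ip1, a regulator of PI3 kinase, at 8.56 against 89.8 CPM, 10.5-fold lower (7.97 to 14), with a log2 ratio of -1.68 in cluster 15 alone. Inflammatory NF-kB targets had a median of -1.66, with Cxcl1 at -2.97 (-3.33 to -2.64) and Ccl3 at -1.90 (-1.97 to -1.84), but the median was -0.14 in cluster 15 alone and -0.86 in cluster 17 alone. This list lay beyond the upper limit in macrophage-like, Kupffer-like (0.76) and hepatocyte or tumour-like cells. In hepatocyte or tumour-like clusters 25 and 29 alone its median was 1.08 and -0.53. Granule genes were higher in 9 of 10 classes, with medians of 1.17 in neutrophil-like cells but 0.19 and 0.14 in clusters 15 and 17 alone, with Camp at 2.00 (1.79 to 2.20) in T-like and Mpo at 2.51 (2.13 to 2.90) in NK-like cells, where these are read as RNA carried over from neutrophil lineage cells. The call held under every alternative in 7 of these 9 classes, and in patrolling monocyte-like cells the median of 0.92 was -0.051 at resolution 0.5. The hepatocyte or tumour-like class joins cluster 29, with Alb and Afp among its top genes and a median of 50139.5 UMIs, and cluster 25, with a median of 1384. Cluster 29 made up 14.3% of the class in control, 5.81% in DU101 and 10.2% in DU102. In this class Limk2 was 4.88-fold higher (3.56 to 6.82), the iron hormone Hamp 9.27-fold lower (7.32 to 11.9) (log2 ratio -1.60 with cells weighted alike) and Itih3 4.52-fold lower (3.83 to 5.36). Their log2 ratios were 2.79, -1.61 and -1.31 in cluster 25 alone and 0.077, -4.40 and -1.56 in cluster 29 alone. Cxcl10 was 3.33-fold higher (2.97 to 3.74) there, but its log2 ratio was -0.10 with every cell weighted alike, 0.90 in cluster 25 and 3.52 in cluster 29. The naive and memory T cell list was the furthest ranked in that class (0.97, beside 3.13 for granule genes), with Tcf7, a T cell gene, at 1.44 (0.39 to 2.62). Whether this RNA was carried over from T-like cells was not tested. The same list lay beyond the lower limit in T-like and B-like cells, with 0.50 and -0.14 in T-like clusters 4 and 6 alone.

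DU102 against control asks the same question for the other treatment, with the same control library and so the same link between sex and treatment. T-like cells were 1.39 (1.31 to 1.48) times as frequent in DU102 and NK-like cells 0.530 (0.486 to 0.577) times. Neutrophil-like cells were 1.46 (1.36 to 1.57) times and their precursor-like cells 4.80 (3.84 to 6.06) times as frequent. In T-like cells the granule enzyme gene Gzmk was 159 against 61.8 CPM, 2.57-fold higher (2.35 to 2.81), with a log2 ratio of 0.74 against control cells with Y-linked RNA and no Xist, 0.32 in cluster 4 alone and 0.61 in cluster 6 alone. Cluster 4, with Gzmk, Cd8a and Ccl5 among its top genes, made up 15.5% of T-like cells in control, 28.3% in DU101 and 34.5% in DU102, and cluster 6, the largest, 59.5%, 50.7% and 45.7%. In B-like cells Pclaf, a factor of DNA replication (ENSMUSG00000040204), was 127 against 8.41 CPM, 15.1-fold higher (9.63 to 24.9), with a log2 ratio of 2.61 when cells were weighted alike. The type I interferon list was higher in 4 of 10 classes. Its median ran from -0.38 in neutrophil-like cells (0.45 in cluster 15 and 0.34 in cluster 17 alone) to 0.67 in hepatocyte or tumour-like cells, and it also lay below the lower percentile limit in monocyte-like cells (-0.047).

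T-like cells made up 22.7% (22 to 23.5) of DU102 cells and NK-like cells 7.38% (6.91 to 7.88), against male control estimates of 12.2% and 8.99%. Neutrophil-like cells were 17.9% (17.2 to 18.7), with cluster 15 at 7.73% and cluster 17 at 10.2%, but the male control estimate of 20.7% was higher still. Precursor-like cells were 4.40% (male control 2.29%), and their log2 ratio of 2.26 became 1.66 when cells needed at least 500 genes. cDC2-like cells were lower, at 0.415 (0.347 to 0.494) times the control share (1.67% against 4.02%), but the male control estimate was 1.48%. Kupffer-like cells were 0.517 (0.454 to 0.589) times, macrophage-like cells 0.576 (0.507 to 0.654) times and monocyte-like cells 0.683 (0.626 to 0.745) times the control share, the last turning to a log2 ratio of 0.68 when each library was clustered on its own. Patrolling monocyte-like cells were 1.08 (0.959 to 1.23) times the control share, but had a log2 ratio of -1.60 under that clustering and -0.28 and -0.30 at resolution 0.5 and 2.0. The male control estimates of these 4 classes were 7.43%, 6.64%, 12.1% and 3.14%, against 3.22%, 3.51%, 8.06% and 5.05% in DU102. B-like cells were 1.32 (1.19 to 1.46) times and plasma-like cells 1.52 (1.04 to 2.24) times, against male control estimates of 7.84% and 1.11% and DU102 shares of 8.29% and 0.672%. cDC1-like cells were 0.728 (0.583 to 0.907), migratory dendritic cell-like cells 0.564 (0.396 to 0.797), pDC-like cells 0.678 (0.580 to 0.792) and mast cell or basophil-like cells 0.886 (0.554 to 1.42) times the control share. Against the male control estimate the log2 ratios of the first 3 were 0.072, 1.54 and 0.94, the other way. For cDC1-like cells the Y-linked ratio behind that estimate was 0.277 (0.214 to 0.353), an interval too wide to show a turn. Their share did turn when each library was clustered on its own (0.45 in log2). Mast cell or basophil-like cells had a log2 ratio of 2.34 when each library was clustered on its own, and their male control estimate was 0.623% against 0.340%. Where the sort or lysis can act, hepatocyte or tumour-like cells were 2.71 (2.33 to 3.15), endothelial-like 0.555 (0.443 to 0.694), stellate or fibroblast-like 0.165 (0.0669 to 0.355) and erythroid-like cells 1.36 (0.944 to 1.99) times the control share, with endothelial-like cells at 1.09 and erythroid-like cells at -0.31 in log2 against male control. The hepatocyte or tumour-like log2 ratio became 0.85 when cells needed at least 500 genes.

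In T-like cells cytotoxic genes were the furthest ranked list in DU102 (0.67, beside 2.51 for granule genes and 1.80 for the sex-linked list, but 0.22 and 0.088 in clusters 4 and 6 alone), with Gzma at 1.45 (1.38 to 1.51). Ccl5, a chemokine of activated T cells, was 7508 against 3438 CPM, 2.18-fold higher (2.16 to 2.21), with log2 ratios of 0.28 and 0.56 in the same clusters. Rnaset2b, a lysosomal ribonuclease gene with a near-copy (Rnaset2a), was lower, at 23.4 against 55.0 CPM, 2.35-fold lower (2.05 to 2.70) in T-like, 15.3 against 66.2 CPM, 4.31-fold lower (3.57 to 5.25) in NK-like and 9.11 against 52.4 CPM, 5.75-fold lower (2.55 to 16.1) in Kupffer-like cells. In NK-like cells Trim12a was 2.06-fold higher (1.80 to 2.37). Cirbp, a cold-inducible RNA-binding protein, was 1.77-fold higher (1.61 to 1.95), though its log2 ratio was -0.57 against control cells with Y-linked RNA and no Xist. The myeloid suppressor list was the furthest ranked in NK-like cells (1.25, beside 2.97 for granule genes and 2.26 for the sex-linked list), a list of myeloid genes, led by Ifitm1 at 1.90 (1.47 to 2.34), and its median was 0.41 with doublets kept. Cell cycle genes lay beyond the upper limit in 3 of 10 classes and beyond the lower limit in 3, macrophage-like, Kupffer-like and NK-like cells. In NK-like clusters 7 and 20 alone their median was -0.23 and -0.016. In B-like cells cell cycle genes had a median of 1.93, beside 2.49 for granule genes (cell cycle 0.95 with cells weighted alike), with Ccnb2 at 3.35 (2.06 to 5.01). Tuba1b, a tubulin, was 2.01-fold higher (1.75 to 2.32), and H2-Eb1 of MHC class II 2.63-fold lower (2.48 to 2.80).

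In pDC-like cells the chemokine receptor Ccr2 was 500.1 against 212 CPM, 2.36-fold higher (2.14 to 2.60), Trim12a 2.09-fold higher (1.72 to 2.55), and Fkbp5, a gene induced by glucocorticoids, 3.31-fold lower (2.62 to 4.22). In macrophage-like cells the cytokine Il1b was 621 against 235 CPM, 2.64-fold higher (2.46 to 2.84), with a log2 ratio of 0.44 when cells needed at least 500 genes, and Hes1 1.77-fold higher (1.61 to 1.94). Spp1, osteopontin, was 4.38-fold lower (3.91 to 4.93), but had a log2 ratio of 0.10 when each library was clustered on its own, -0.24 with at least 500 genes, -0.088 and -0.29 at up to 5% and 20% mitochondrial UMIs, -0.25 with doublets kept and -0.43 and -0.17 at resolution 0.5 and 2.0. The cytotoxic list was the furthest ranked in macrophage-like (0.96) and Kupffer-like cells (1.61), beside granule medians of 2.11 and 2.95 and a sex-linked median of 1.34 in macrophage-like cells, with cytotoxic medians of 0.25 at up to 20% mitochondrial UMIs in the former and 0.71 with cells weighted alike in the latter, and with the lymphocyte genes Nkg7 at 1.38 (0.97 to 1.80) and Ccl5 at 2.11 (1.91 to 2.31). In Kupffer-like cells Slfn5 was 1.90-fold higher (1.55 to 2.33), Rcor1 2.44-fold higher (1.49 to 3.97) and Sft2d1 3.10-fold lower (1.77 to 5.84). In patrolling monocyte-like cells Rif1 was 2.42-fold higher (1.74 to 3.41) (log2 ratio 0.59 at resolution 0.5), the formyl peptide receptor Fpr1 2.07-fold higher (1.61 to 2.68) and the stress-induced Gdf15 3.17-fold lower (2.28 to 4.48) (log2 ratio -0.85 with cells weighted alike). In monocyte-like cells the NF-kB targets were the furthest ranked list (-0.51, beside 1.36 for the sex-linked list and 0.39 for granule genes), and among them Cxcl1 was 15.7 against 64.5 CPM, 4.11-fold lower (3.36 to 5.07), with a log2 ratio of -1.23 under separate clustering. AI839979 was 2.11-fold higher (1.84 to 2.43). Pf4 was 2.31-fold higher (2.11 to 2.52), but lower in 5 alternatives, down to a log2 ratio of -1.76.

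In neutrophil-like cells, where the median of all genes was -0.37, Lyz2 (lysozyme) was 9475 against 2649 CPM, 3.58-fold higher (3.51 to 3.64), but with log2 ratios of 0.39 in cluster 15 and 0.91 in cluster 17 alone. Gstp3 was 5.44-fold higher (4.07 to 7.43). Stfa1 was 16.8-fold lower (15.8 to 18.0) and its relative Cstdc5 14.1-fold lower (13.1 to 15.1), both uncertain as near-copies. In cluster 15 alone the log2 ratio of Stfa1 was -2.83. Granule genes were the furthest ranked list there (1.23, but 0.24 and 0.20 in clusters 15 and 17 alone) and were higher in 10 of 10 classes, with Camp at 3.49 (3.27 to 3.71) in NK-like cells and a call that held under every alternative in 9 of these 10. Hepatocyte RNA was higher in 8 of 10 classes, with Alb, albumin, at 1.89 (1.40 to 2.42) in T-like cells, and both are read as carried-over RNA outside the cells that make them. Heat shock and dissociation genes were lower in 7 of 10 classes, with Fosb at -1.51 (-2.07 to -0.97) in B-like cells, and beyond the upper limit in hepatocyte or tumour-like cells (0.64). The lower call held under every alternative in 2 of these 7 classes. Against control cells with Y-linked RNA and no Xist the list's median was above 0 in macrophage-like, T-like, NK-like and B-like cells (0.37, 0.10, 0.041 and 0.019). Chemokines were lower in 5 of 8 classes, with Cxcl9 at -4.91 (-10.26 to -2.32) in patrolling monocyte-like cells, and lysosome genes in 5 of 10, with Cd36 at -2.65 (-3.70 to -1.68) in neutrophil-like cells, where the lysosome median was -1.04 but -0.15 in cluster 15 and -0.47 in cluster 17 alone. These calls held under every alternative in 1 of these 5 classes for chemokines and 0 of these 5 for lysosome genes, and both lists lay beyond the upper limit in hepatocyte or tumour-like cells (0.86 and 0.25). The chemokine median turned against the same control cells in monocyte-like and T-like cells (0.038 and 0.053), as did the lysosome median in T-like cells (0.20, and 0.079 in cluster 6 alone), and the chemokine median turned in macrophage-like cells in 6 alternatives. In hepatocyte or tumour-like cells Sprr1a was 112 against 12 CPM, 9.32-fold higher (7.0 to 12.7) (log2 ratio 1.27 with cells weighted alike), Cps1 of the urea cycle 7.35-fold lower (5.78 to 9.42) and Sardh 2.05-fold lower (1.81 to 2.31). In clusters 25 and 29 alone the log2 ratios were -4.74 and -2.55 for Cps1, 3.35 and 2.93 for Sprr1a and -2.08 and -0.57 for Sardh. Cxcl10 was 3.03-fold higher (2.71 to 3.40), with a log2 ratio of -0.31 with every cell weighted alike, but 1.48 and 1.79 in clusters 25 and 29. The naive and memory T cell list was the furthest ranked in that class (0.98, beside 3.27 for granule genes), with Bcl2 at 1.47 (0.73 to 2.29). Whether this RNA was carried over from T-like cells was not tested. The same list lay beyond the lower limit in monocyte-like, T-like and B-like cells, but its median was 0.17 and 0.30 in T-like clusters 4 and 6 alone. In all, 121 of 235 scored pairs of list and class lay at or beyond the percentiles of random lists, 70 higher and 51 lower. The 70 include 8 for hepatocyte RNA, 8 for the sex-linked list and 10 for granule genes.

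DU101 and DU102 were also set side by side, a comparison of 2 treated libraries that were both almost free of Xist. Plasma-like cells were 5.59 (4.39 to 7.19) times and cDC2-like cells 2.29 (1.94 to 2.72) times as frequent in DU101 as in DU102. B-like cells were 0.415 (0.371 to 0.464) times, neutrophil-like cells 0.625 (0.584 to 0.668) times and hepatocyte or tumour-like cells, which the sort can set, 0.474 (0.419 to 0.535) times. T-like cells were 1.20 (1.14 to 1.26) times and NK-like cells 1.08 (0.986 to 1.18) times. Type I interferon genes were higher in DU101 in 9 of 10 classes.

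The interferon medians were 0.88 in neutrophil-like, 0.73 in pDC-like, 0.72 in monocyte-like, 0.72 in T-like and 0.25 in B-like cells, with Ifi44 at 1.78 (1.05 to 2.58) in T-like and Rsad2 at 1.97 (1.42 to 2.57) in Kupffer-like cells. The median of all genes in neutrophil-like cells was 0.14. Whether calls held under the alternatives is given only for the comparisons against control, not for DU101 over DU102. In monocyte-like cells the interferon and interferon-gamma medians of DU101 over control turned under separate clustering. MHC class II genes were higher in 6 of 10 classes and the furthest ranked list in neutrophil-like (1.02) and hepatocyte or tumour-like cells (0.76), with H2-Eb1 at 1.92 (1.68 to 2.16) in T-like cells. Whether class II RNA in these 3 classes was made there or carried over from other classes was not tested. In single clusters the class II median was 1.15 and 0.84 in neutrophil-like clusters 15 and 17 and 1.22 and 0.43 in T-like clusters 4 and 6. It was 0.71 and -1.07 in NK-like clusters 7 and 20. Heat shock and dissociation genes were higher in 9 of 10 classes and NF-kB targets in 7 of 10, with Atf3 at 1.82 (1.56 to 2.1) in NK-like and the chemokine Cxcl1 at 3.58 (1.62 to 6.68) in Kupffer-like cells. The interferon-gamma list was higher in 6 of 10 classes (Iigp1 1.85 (1.29 to 2.46) in monocyte-like cells), chemokines in 5 of 8 (Ccl8 2.28 (2.02 to 2.56) in macrophage-like cells) and the unfolded protein list in 5 of 10 (Ddit3 0.86 (0.58 to 1.14) in macrophage-like cells). Hepatocyte RNA was lower in 9 of 10 classes, with Alb at -1.56 (-1.94 to -1.19) in T-like cells, and granule genes in 8 of 10, with Camp at -1.31 (-1.47 to -1.16) in NK-like cells, both read as carried-over RNA in these classes. Over all pairs, 110 of 226 lay beyond the percentiles, 74 higher and 36 lower. The 36 include 9 for hepatocyte RNA and 8 for granule genes, and the 74 include 1 for granule genes.

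Among T-like cells, Cd8a or Cd8b1, the chains of CD8, was seen in 47.0% (44.6 to 49.4) of control, 52.3% (50.7 to 53.9) of DU101 and 57.3% (55.4 to 59.2) of DU102 cells. Median depths in T-like cells were 5144, 3853 and 4547.5 UMIs. Thinned to 1000 UMIs per cell, the shares were 29.6% (27.4 to 31.8), 38.2% (36.7 to 39.8) and 37.3% (35.4 to 39.2). B-like cells, which should lack CD8 and had median depths of 3187, 2891 and 3013 UMIs, gave 0.313%, 0.858% and 0.428% at that depth. Cd4 was seen in 8.81%, 9.13% and 8.79% of thinned T-like cells, with overlapping intervals, against 0.157%, 0% (up to 0.788%) and 0.107% of B-like cells. Foxp3, the factor of regulatory T cells, was seen in 3.92% (3.03 to 4.97), 2.67% (2.17 to 3.24) and 3.41% (2.74 to 4.19), against 0.157%, 0.215% and 0% (up to 0.394%) of B-like cells. Thinned in the same way, Il2ra was seen in 3.73%, 2.23% and 2.28% of T-like cells, Ikzf2 in 16.9%, 14.5% and 12.9%, and Cd40lg in 3.06%, 4.80% and 2.51%. Ctla4 was seen in 10.2%, 12% and 9.18%, and Tnfrsf4 in 10.1%, 9.48% and 9.03%. The highest share of thinned B-like cells with any of these 5 genes was 1.29%, for Ctla4 in DU101. Cells of both sexes make up the control values.

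Cd274, Ptprc and Myc had been fixed for every class. Cd274 encodes PD-L1, a ligand that restrains T cells. Its ratio of DU101 over control was 0.309 (0.271 to 0.351) in neutrophil-like, 1.14 (0.991 to 1.32) in monocyte-like, 1.19 (1.02 to 1.39) in patrolling monocyte-like, 1.00 (0.817 to 1.23) in macrophage-like, 1.15 (0.732 to 1.79) in Kupffer-like, 1.00 (0.542 to 1.84) in pDC-like, 1.24 (1.06 to 1.46) in T-like, 1.29 (1.06 to 1.55) in NK-like, 0.95 (0.707 to 1.27) in B-like and 0.967 (0.449 to 2.12) in hepatocyte or tumour-like cells. For DU102 over control it was 0.293 (0.262 to 0.327) in neutrophil-like, 0.768 (0.647 to 0.908) in monocyte-like, 1.14 (0.968 to 1.33) in patrolling monocyte-like, 1.14 (0.911 to 1.42) in macrophage-like, 1.09 (0.632 to 1.82) in Kupffer-like, 0.629 (0.289 to 1.29) in pDC-like, 0.929 (0.779 to 1.11) in T-like, 1.47 (1.22 to 1.78) in NK-like, 0.488 (0.366 to 0.649) in B-like and 0.528 (0.228 to 1.21) in hepatocyte or tumour-like cells. In neutrophil-like cells the log2 ratio of Cd274 was -1.70 for DU101 and -1.77 for DU102, and with every cell weighted alike -1.18 and -0.87. In cluster 15 alone it was -0.12 (-0.32 to 0.083) and 0.076 (-0.094 to 0.25), and in cluster 17 alone -0.74 (-1.33 to -0.12) and -1.18 (-1.75 to -0.59). Against control cells with Y-linked RNA and no Xist it was -0.88 and -0.96 in neutrophil-like, 1.30 and 0.73 in monocyte-like and 0.97 and 0.55 in T-like cells. In monocyte-like cells the log2 ratio for DU101 was 0.19 but between -0.64 and -0.15 in 5 alternatives, and for DU102 it was -0.38 but 1.02 when each library was clustered on its own. For DU101 it was -0.19 (-0.83 to 0.48) and 0.31 (-0.030 to 0.66) in T-like cells of clusters 4 and 6 and 0.33 (0.038 to 0.63) and -0.33 (-1.22 to 0.49) in NK-like cells of clusters 7 and 20. For DU102 it was -0.45 (-1.90 to 1.06) and -2.30 (-5.64 to 0.18) in hepatocyte or tumour-like cells of clusters 25 and 29.

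Ptprc, the gene of the sorted protein, had ratios of DU101 over control of 0.729 (0.702 to 0.757) in neutrophil-like, 1.13 (1.09 to 1.16) in monocyte-like, 1.06 (1.01 to 1.10) in patrolling monocyte-like, 1.27 (1.21 to 1.33) in macrophage-like, 1.15 (1.01 to 1.31) in Kupffer-like, 0.929 (0.874 to 0.986) in pDC-like, 1.04 (1.01 to 1.06) in T-like, 1.04 (1.02 to 1.07) in NK-like, 0.908 (0.835 to 0.987) in B-like and 1.98 (1.60 to 2.47) in hepatocyte or tumour-like cells. For DU102 over control the Ptprc ratios were 0.803 (0.776 to 0.830) in neutrophil-like, 1.33 (1.29 to 1.37) in monocyte-like, 1.25 (1.20 to 1.31) in patrolling monocyte-like, 1.38 (1.31 to 1.46) in macrophage-like, 1.44 (1.25 to 1.65) in Kupffer-like, 1.13 (1.06 to 1.19) in pDC-like, 1.19 (1.16 to 1.22) in T-like, 1.17 (1.14 to 1.20) in NK-like, 1.11 (1.04 to 1.19) in B-like and 1.76 (1.43 to 2.18) in hepatocyte or tumour-like cells. In neutrophil-like cells these ratios are read against the median of all genes, which was itself below control. For DU102 the Ptprc log2 ratio of -0.32 lay above that median. Within the neutrophil-like clusters Ptprc was higher than control, with log2 ratios of 0.18 (0.10 to 0.26) for DU101 and 0.47 (0.41 to 0.53) for DU102 in cluster 15 and 0.19 (0.081 to 0.29) and 0.31 (0.21 to 0.41) in cluster 17. In hepatocyte or tumour-like cells the log2 ratios were 0.11 and 0.024 at up to 5% mitochondrial UMIs. Ptprc in that class was at 28.5 CPM in control, 56.4 in DU101 and 50.1 in DU102, against 931 in T-like cells of control.

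Myc, the gene of the transcription factor in the name of the mouse model, had ratios of DU101 over control of 0.648 (0.339 to 1.23) in neutrophil-like, 0.896 (0.664 to 1.20) in monocyte-like, 0.613 (0.217 to 1.63) in patrolling monocyte-like, 0.904 (0.698 to 1.17) in macrophage-like, 0.699 (0.375 to 1.25) in Kupffer-like, 0.474 (0.0451 to 2.90) in pDC-like, 0.696 (0.616 to 0.785) in T-like, 1.07 (0.966 to 1.18) in NK-like, 0.912 (0.747 to 1.11) in B-like and 1.39 (1.21 to 1.60) in hepatocyte or tumour-like cells. For DU102 over control the Myc ratios were 0.423 (0.225 to 0.796) in neutrophil-like, 0.427 (0.282 to 0.633) in monocyte-like, 0.833 (0.322 to 2.1) in patrolling monocyte-like, 0.907 (0.674 to 1.21) in macrophage-like, 0.743 (0.357 to 1.43) in Kupffer-like, 1.63 (0.416 to 6.77) in pDC-like, 0.667 (0.586 to 0.759) in T-like, 0.663 (0.587 to 0.747) in NK-like, 0.498 (0.411 to 0.602) in B-like and 1.28 (1.12 to 1.46) in hepatocyte or tumour-like cells. In monocyte-like cells the log2 ratio for DU102 was -1.23, but -0.17 when each library was clustered on its own and -0.25 at up to 20% mitochondrial UMIs. In neutrophil-like cells it was -1.24, with -0.99 (-2.60 to 0.37) in cluster 15 alone but 0.49 (-1.59 to 3.65) in cluster 17 alone, the latter from 2 and 17 UMIs. For DU101 the neutrophil-like log2 ratio of Myc was -0.63 (-1.56 to 0.30). In clusters 15 and 17 alone it was 0.56 (-0.60 to 1.67) and 0.36 (-1.92 to 3.61). In hepatocyte or tumour-like cells of cluster 25 alone it was -0.029 (-0.24 to 0.19) for DU101 and 0.19 (-0.021 to 0.40) for DU102, and in those of cluster 29 0.61 (-0.014 to 1.23) and 0.80 (0.31 to 1.32). The reads were not split between the endogenous gene and any transgene.

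**Figure D3:**
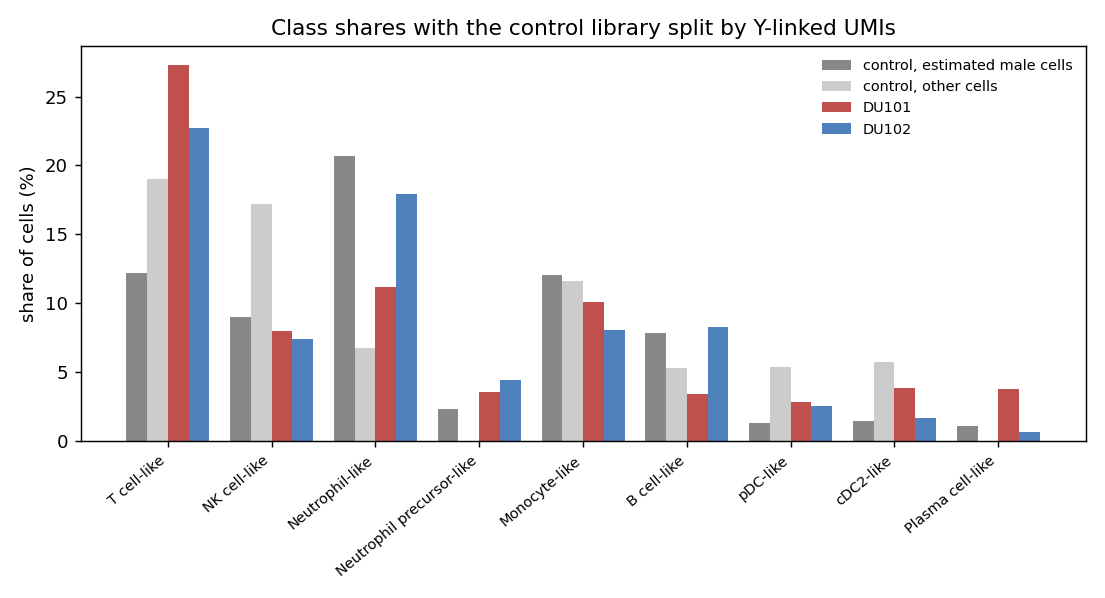
Share of cells (percent, vertical axis) in 9 classes for the estimated male part of control, the rest of control, DU101 and DU102. The male part of control held 20.7% neutrophil-like and 12.2% T-like cells, against 17.9% and 22.7% in DU102.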

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

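The rule that picked these results and the values within single clusters were chosen only after the results were seen. The results are gene lists whose median log2 ratio against control went in opposite directions, each by at least 1.5-fold, in a pair of classes. The difference between the classes was not tested, since each group has 1 library. In 6 of the 7 cases the lower class is the neutrophil-like class, whose clusters differ in share between the libraries.

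In DU101 over control, inflammatory NF-kB targets had a median of -1.66 in neutrophil-like cells and 0.76 in Kupffer-like cells. Within cluster 15 the neutrophil-like median was -0.14 and within cluster 17 -0.86. Heat shock and dissociation genes had -0.82 in neutrophil-like and 0.70 in hepatocyte or tumour-like cells, with -0.12 and -0.13 within clusters 15 and 17 and 0.43 and 0.47 within hepatocyte or tumour-like clusters 25 and 29.

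In DU102 over control, chemokines had a median of -1.56 in neutrophil-like and 0.86 in hepatocyte or tumour-like cells, with -0.47 in cluster 15 and too few members for a score in cluster 17. Heat shock and dissociation genes had -1.18 and 0.64 in the same classes, with -0.39 and -0.84 in clusters 15 and 17. Immune checkpoint ligands had -1.25 and 0.62, with -0.0036 and -0.049. Myeloid suppressor genes had -1.04 in neutrophil-like and 1.25 in NK-like cells, with 0.10 and -0.21 in clusters 15 and 17. Naive and memory T cell genes had -0.73 in B-like and 0.98 in hepatocyte or tumour-like cells. The hepatocyte or tumour-like class joins clusters of very unequal depth, so a few RNA-rich cells weigh heavily in it. In its clusters 25 and 29 alone the checkpoint ligand median was 0.97 and 0.18, the chemokine median 0.81 and 1.36 and the heat shock median 0.42 and 0.52. For naive and memory T cell genes cluster 25 had 1.35 and cluster 29 too few members for a score, and for myeloid suppressor genes NK-like clusters 7 and 20 had 0.78 and 1.75.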

How the results depend on the processing

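The alternatives with 1 cluster alone of neutrophil-like, T-like, NK-like or hepatocyte or tumour-like cells, control cells with Y-linked UMIs and no Xist, the estimated male part of control, and shares without low-UMI hepatocyte or tumour-like and unnamed clusters were chosen only after the results were seen. The 279 results were recomputed under each alternative that applies to them. Reversed means the opposite sign in a share whose own 95% interval excludes a ratio of 1, a gene that also passed the size rule, or a list beyond the percentiles, so counts of reversals leave out sign differences in other results. A share or gene counts as moved outside its own 95% interval, and a list median as weaker when it no longer lies beyond the percentiles of random lists. Values here are log2 ratios over control unless said otherwise, and for those given by value the cause was not tested.

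With at least 500 genes per cell, shares that moved on the same side in DU101 had log2 ratios of neutrophil precursor-like 1.59. For DU102, shares that moved on the same side were neutrophil precursor-like 1.66, monocyte-like -0.21, Kupffer-like -1.16 and hepatocyte or tumour-like 0.85. In DU101, list medians reversed were chemokines -0.0091 in monocyte-like cells. DU102 list medians reversed to chemokines 0.022 in macrophage-like cells. Among genes, DU102 reversed for Pf4 -0.27 in monocyte-like cells. At up to 20% mitochondrial UMIs, DU102 shares that moved on the same side had log2 ratios of monocyte-like -0.20. In DU101, list medians reversed were interferon-gamma -0.11 in monocyte-like, chemokines -0.26 in monocyte-like and heat shock -0.065 in monocyte-like cells. Among genes, DU101 reversed for Cxcl9 -0.78 in monocyte-like cells. Reversed list medians of DU102 were chemokines 0.032 in macrophage-like cells. Reversed genes of DU102 were Pf4 -1.43 in monocyte-like cells. At up to 5% mitochondrial UMIs, for DU101, shares that reversed were pDC-like 0.11. DU101 shares that moved on the same side had log2 ratios of macrophage-like -0.080, Kupffer-like -0.66 and cDC1-like 0.18. Shares that moved on the same side in DU102 had log2 ratios of cDC1-like -0.84 and pDC-like -0.15. List medians of DU101 that reversed were chemokines -0.13 in monocyte-like, MHC class II -0.22 in hepatocyte or tumour-like and chemokines -0.30 in hepatocyte or tumour-like cells. DU101 genes reversed to Cxcl9 -0.085 in monocyte-like cells. DU102 list medians reversed to chemokines 0.053 in macrophage-like cells. Among genes, DU102 reversed for Pf4 -1.76 in monocyte-like cells. Against the estimated male part of control, DU101 shares that reversed had log2 ratios of pDC-like 1.11, endothelial-like 1.01 and stellate or fibroblast-like 0.41. Shares that reversed in DU102 had log2 ratios of neutrophil-like -0.20, cDC1-like 0.072, cDC2-like 0.17, migratory dendritic cell-like 1.54, pDC-like 0.94, plasma-like -0.72 and endothelial-like 1.09. These labels and their count take the male estimates as exact. Given the intervals of the Y-linked ratios, stellate or fibroblast-like cells in DU101 and cDC1-like and cDC2-like cells in DU102 show no clear reversal. For DU101, shares that took the opposite sign from an interval that holds 1 were cDC2-like 1.37. DU102 shares that took the opposite sign from an interval that holds 1 had log2 ratios of erythroid-like -0.31. Shares that moved on the same side in DU101 had log2 ratios of neutrophil-like -0.88, neutrophil precursor-like 0.64, patrolling monocyte-like 0.80, Kupffer-like -1.10, cDC1-like 1.01, migratory dendritic cell-like 2.92, T-like 1.16, NK-like -0.17, B-like -1.19, plasma-like 1.76, mast cell or basophil-like 0.34, hepatocyte or tumour-like 0.71 and erythroid-like -1.98. For DU102, shares that moved on the same side were neutrophil precursor-like 0.94, patrolling monocyte-like 0.68, Kupffer-like -1.21, T-like 0.90, NK-like -0.28, B-like 0.080, mast cell or basophil-like -0.87, hepatocyte or tumour-like 1.79 and stellate or fibroblast-like -1.32.

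Against control cells with Y-linked UMIs and no Xist, DU101 list medians reversed to chemokines -0.051 in monocyte-like cells. Reversed list medians of DU102 were chemokines 0.038 in monocyte-like, heat shock 0.37 in macrophage-like, chemokines 0.053 in T-like, heat shock 0.10 in T-like, lysosome 0.20 in T-like, heat shock 0.041 in NK-like and heat shock 0.019 in B-like cells. Among genes, DU102 reversed for Cirbp -0.57 in NK-like cells. With doublets kept, DU101 shares that moved on the same side had log2 ratios of monocyte-like -0.087 and NK-like -0.69. Shares that moved on the same side in DU102 had log2 ratios of monocyte-like -0.25. Reversed list medians of DU101 were MHC class II -0.43 in monocyte-like cells. DU101 genes reversed to Cxcl9 -0.75 in monocyte-like cells. Reversed genes of DU102 were Pf4 -1.41 in monocyte-like cells. With each library clustered on its own, for DU101, shares that reversed were monocyte-like 0.13, patrolling monocyte-like -1.22 and macrophage-like 0.44. DU102 shares that reversed had log2 ratios of monocyte-like 0.68 and cDC1-like 0.45. Shares that took the opposite sign from an interval that holds 1 in DU102 had log2 ratios of patrolling monocyte-like -1.60 and mast cell or basophil-like 2.34. For DU101, shares that moved on the same side were T-like 0.65 and NK-like -1.03. DU102 shares that moved on the same side had log2 ratios of neutrophil-like 0.44, macrophage-like -1.15, T-like 0.59 and NK-like -1.24. Reversed list medians of DU101 were type I interferon -0.16 in monocyte-like, interferon-gamma -0.48 in monocyte-like, chemokines -0.76 in monocyte-like and MHC class II -0.024 in hepatocyte or tumour-like cells. Among genes, DU101 reversed for Cxcl9 -2.65 in monocyte-like and Ifit2 -1.25 in monocyte-like cells. In DU102, list medians reversed were chemokines 0.26 in macrophage-like cells. Reversed genes of DU102 were Spp1 0.10 in macrophage-like cells. With list members of at least 100 UMIs, reversed list medians of DU102 were lysosome 0.0018 in patrolling monocyte-like cells.

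With every cell weighted alike, list medians of DU101 that reversed were chemokines -0.58 in hepatocyte or tumour-like cells. Reversed genes of DU101 were Cxcl10 -0.10 in hepatocyte or tumour-like cells. Among genes, DU102 reversed for Cxcl10 -0.31 in hepatocyte or tumour-like cells. In neutrophil-like cells of cluster 15 alone, reversed list medians of DU101 were lysosome 0.086 in neutrophil-like cells. Reversed genes of DU102 were Cd274 0.076 in neutrophil-like cells. In those of cluster 17 alone, among genes, DU102 reversed for Myc 0.49 in neutrophil-like cells. In T-like cells of cluster 6 alone, DU102 list medians reversed to lysosome 0.079 in T-like cells. In NK-like cells of cluster 20 alone, reversed genes of DU101 were Ccl1 -0.87 in NK-like cells. At resolution 0.5, for DU101, shares that reversed were patrolling monocyte-like -0.055 and erythroid-like 0.49. DU102 shares that took the opposite sign from an interval that holds 1 had log2 ratios of patrolling monocyte-like -0.28. Shares that moved on the same side in DU101 had log2 ratios of cDC1-like 0.081. For DU102, shares that moved on the same side were cDC1-like -1.01. List medians of DU101 that reversed were granules -0.051 in patrolling monocyte-like cells. In DU102, list medians reversed were lysosome 0.013 in patrolling monocyte-like and chemokines 0.10 in macrophage-like cells. At resolution 2.0, for DU102, shares that took the opposite sign from an interval that holds 1 were patrolling monocyte-like -0.30. DU101 shares that moved on the same side had log2 ratios of monocyte-like -0.070. Shares that moved on the same side in DU102 had log2 ratios of monocyte-like -0.10. In DU101, list medians reversed were heat shock -0.068 in monocyte-like cells. DU102 list medians reversed to chemokines 0.11 in macrophage-like cells. Reversed genes of DU102 were Pf4 -1.56 in monocyte-like cells.

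Reversals by alternative were 3 with at least 500 genes, 7 and 6 at up to 5% and 20% mitochondrial UMIs, 3 with doublets kept, 5 and 3 at resolution 0.5 and 2.0, 13 with separate clustering, 3 with every cell weighted alike, 10 against the estimated male part of control, 9 against control cells with Y-linked UMIs, 1 with list members of at least 100 UMIs and 5 with single clusters. Weaker list medians numbered 12 with every cell weighted alike, 8 against control cells with Y-linked UMIs, 7 with doublets kept, 7 and 5 at up to 5% and 20% mitochondrial UMIs, 6 with separate clustering, 5 with at least 500 genes, 4 and 4 at resolution 0.5 and 2.0, 3 and 2 with list members of at least 100 and 10 UMIs and 10 with single clusters. With edgeR TMM factors none of 223 results reversed and 14 moved. The sign did change for 2 genes that were under the size rule or had an interval that holds 1. These factors were 1.16, 0.981 and 0.883 for neutrophil-like cells of control, DU101 and DU102. Totals without carried-over and housekeeping RNA reversed none and moved 3. Shares without low-UMI hepatocyte or tumour-like and unnamed clusters all stayed within their intervals (36 results).

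Thinned to 1000 UMIs, Cd8a or Cd8b1 was seen in 29.6%, 38.2% and 37.3% of T-like cells in control, DU101 and DU102, and thinned to 500 UMIs in 17.8%, 25.6% and 24.4%. Both treated libraries stayed above control. Depth limits all such shares, and classes with few cells, such as Kupffer-like cells at a median of 1100.0 UMIs in DU102, score fewer lists. No paired analysis was possible because each group has 1 library and the labels pair no samples. Naming by the authors' annotation against own clusters was not run, since no annotation per barcode was among the data used here.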

Other observations

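The tests of the neutrophil and T-like patterns were chosen only after the results were seen, as were the genes of the first 2 paragraphs and the use of control cells split by sex-linked RNA. The genes Rnaset2b and Hebp1 belong to none of the lists. Rnaset2b was at 66.2 CPM in control, 116 in DU101 and 15.3 in DU102 NK-like cells. In T-like cells it was at 55.0, 103 and 23.4 CPM, and in B-like cells at 21.9, 48.9 and 3.90 CPM. Hebp1 was lower in DU101 than in control, at 104, 11.9 and 100.3 CPM in monocyte-like cells, 105, 10.7 and 56.1 in patrolling monocyte-like cells and 157, 78.8 and 132 in macrophage-like cells. No explanation was tested for these genes.

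Cluster 24, which took no name and whose top genes include Lipg, Fcrl5, Cd300e and Cxcl13, held 3.01% of control, 0.290% of DU101 and 2.51% of DU102 cells, or 306, 40 and 288 cells. It held an estimated 6.41% of the male part of control and 0.750% of the rest, so both treated shares were below the male control estimate. Cluster 13, unnamed, held 1, 26 and 0 cells and is almost wholly of 1 library.

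Type I interferon response genes were higher in DU101 than in control in all 10 classes. The test of free RNA carried from 1 class into all others assumed that it adds a like number of UMIs to every cell. The largest number added per cell, 11.4 in macrophage-like cells, was 7.42 times the smallest, 1.53 in B-like cells. The granule gene Camp, read as carried over, did not meet that assumption in DU101. It was at 551 CPM in hepatocyte or tumour-like and 83.2 CPM in B-like cells, with median depths of 3321 and 2891 UMIs. The spread in added UMIs therefore cannot decide whether carry-over was the whole cause. Nor can it exclude a carried-over part of like size in every class. Such a part could make up the rise in B-like cells and much of that in hepatocyte or tumour-like (2.01) and Kupffer-like cells (2.38). DU101 was also compared with control cells with Y-linked RNA and no Xist, in the 6 classes with at least 100 of them. The list stayed at or beyond the upper percentile limit in 6 of 6, with medians from 0.71 to 1.28. In these classes that argues against the mix of sexes in control as the whole cause. Patrolling monocyte-like, Kupffer-like and pDC-like cells (59, 42 and 35 such cells) and hepatocyte or tumour-like cells were not scored. In Kupffer-like cells the mix stays open, since within control the median of Y-linked over Xist cells was 0.97, beside 0.84 for DU101 over control. Whether animals pooled in the control library differ from each other as much as DU101 differs from control stays open: within control, the median between cells with Y-linked RNA and cells with Xist was under 0.5 times the DU101 value in size in 2 of 9 classes, ran from -1.03 in monocyte-like to 0.97 in Kupffer-like cells, was at least as large in 4, and lay below 0, against the direction of DU101, in 8 of 9. A response to DU101 may lie behind the pattern as well, and with 1 library per group it cannot be told apart from a difference between animals.

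Clusters 17, 18 and 26, neutrophil-like cells with Retnlg and Ly6g and neutrophil precursor-like cells, made up 2.65% of control, 10.5% of DU101 and 14.6% of DU102 cells. More blood left in a treated sample stays open. The erythroid-like share was 0.427 times that of control in DU101, but red cells were lysed and the share turned the other way at resolution 0.5, and in DU102 it was 1.36 times, with an interval that holds 1. The male part of control held an estimated 6.61% (5.58 to 7.32), above 0.5 times the lower treated share (5.25%), against 0.0169% in the rest of control. A difference in neutrophil content between animals, by sex or otherwise, therefore stays open, beside an effect of the treatments that was not tested.

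T-like cells were more frequent and NK-like cells less frequent in both treated libraries than in control, with 1.17 T-like cells per NK-like cell in control, 3.43 in DU101 and 3.08 in DU102. Growth or loss of other classes alone would move both shares alike, and it is argued against because T-like cells were 53.9% of T-like and NK-like cells in control, 77.4% in DU101 and 75.5% in DU102 (74.0 to 76.9). These percentages restate the shares above and are no separate test, and a difference in either class itself stays open. A difference between the animals pooled in control stays open: the male part of control had an estimated 1.36 T-like cells per NK-like cell (1.16 to 1.59), an interval that holds the bound of 1.54 set for excluding it. An effect of the treatments may contribute and was not tested.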
